A study of Homo sapiens with 9 samples.

How the data were processed

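Messenger RNA was sequenced from 143B, an established human osteosarcoma cell line, in 9 libraries that form 3 groups of 3. The control group was taken at 0 h, and the other groups received 0.5 µM of XD23, a compound known from the labels by its code name alone, for 24 h or 48 h. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was captured on oligo(dT) beads and fragmented, and paired-end libraries were built with random hexamer primers. The labels state neither a strand-specific kit nor strand-specific counting, so reads of overlapping and antisense genes cannot be told apart. The labels name no vehicle and no untreated cells at 24 h or 48 h, so time in culture and the compound change together in each comparison. Nothing in the labels says that the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries.

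The values used are FPKM, fragments scaled to gene length and to the depth of the library, which the authors deposited as 1 table of 36810 genes and 9 libraries, with replicates kept apart. HISAT2, featureCounts, Subread and DESeq2 and the build hg38 are named in the submitters' processing notes, while versions, settings and the annotation release are not given in the sources used here. Gene identifiers were paired with names for 36724 genes, and 35585 were found in GENCODE release 29 (build GRCh38), which gave gene types, positions and exon lengths. Of these, 17169 were protein-coding.

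The depth behind the FPKM was worked out from the values. Multiplying each value by the summed exon length in GENCODE and by 1 total per library gave whole fragments, to within 0.001 of a fragment, for 20926 genes (58.8% of those with a GENCODE length). For another 15882 genes the smallest length that made all 9 values whole was used, so the fragment numbers of those genes rest on that choice. The totals were 18341542 to 22901830 fragments per library, and the recovered fragments summed to 99.96% of the total in each library. A single fragment on a gene of 1 kilobase was worth 0.0437 to 0.0545 FPKM. A level of 1 FPKM therefore rests on few fragments in short genes, and small RNAs are reported with their fragment numbers.

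Genes were tested on log2(FPKM + 1) if they had at least 1 FPKM in at least 3 of the 9 libraries, which left 13657 genes, 10868 of them protein-coding. Fold changes are on that log2 scale with a pseudocount of 1, which understates the changes of genes with low values. A linear model with 1 mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a trend), leaving 6 residual degrees of freedom. P-values are two-sided with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. Errors beside a log2 fold change are standard errors from this model, and errors beside FPKM are SD over 3 libraries. DKK1, named in the title of the series, was also tested with a two-sided exact permutation test, for which the smallest possible p with 3 against 3 libraries is 0.1.

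Lists of genes (45) were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They held 1144 different genes, of which 21 matched no gene in the table, and some genes stood in several lists. The lists cover the Wnt pathway, the cell cycle, cell death, stress responses, metabolism, inflammation, matrix and bone, and markers of other cell types. Each list with at least 5 tested members (42 lists) was compared with the other genes using camera in limma with a preset correlation between genes of 0.01, two-sided, with adjustment over the lists. Camera with an estimated correlation was run as an alternative. The rotation test fry, which asks whether the genes of a list move one way and does not compare them with other genes, was run beside it, so its counts answer another question. For every list, the members called over all genes and those called with p adjusted over the list alone were counted. The rule for naming genes took, for each comparison, the 8 highest and the 8 lowest fold changes among called genes with a mean of at least 1 FPKM, a symbol that is not a clone name and no overlap between the 3 values of each group. It added up to 3 members from each called list and from the 4 Wnt lists, and always DKK1, CTNNB1, AXIN2, LEF1, MYC and CCND1. Some genes with near-identical copies are marked as uncertain, because the counting could split or misplace their reads. The marking is not exhaustive, so a gene without it can have such copies too.

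The alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, array weights, a fit to only the groups compared, the replicate number as a block, leaving out each library in turn, and a threshold of 1 on the absolute log2 fold change. Added after seeing the data were voom weights on the recovered whole fragments, the same without the third 24 h library, a correction for gene length, and protein-coding genes only. The replicate numbers did not pair the libraries, so the block stands only among the alternatives. Correlations of the 24 h and 48 h responses were set beside 100 simulations of unchanged groups that share the controls. These drew genes independently, with 1 spread per gene for all 9 libraries. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom 2.12 or more over genes with at least 20 fragments), so all 9 were kept as separate libraries.

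The scripts were tested on simulated fragments with known changes, drawn with the levels and spread of the genes measured here. In the simulation of 24 h against control with 13346 genes tested, 42% of 50 genes changed 1.25-fold, 68% of those changed 1.5-fold and 88% of those changed 2-fold were recovered, with 5 false calls among 147. In that of 48 h against control with 13345 genes tested, the shares were 28%, 82% and 86%, with 6 false calls among 152. A list of 25 genes changed 1.2-fold was called in both simulations, with 1 and 0 calls among the other lists. Genes were drawn independently, while the measured lists had estimated correlations of up to 0.87 (ribosomal proteins). The simulations therefore do not show how often camera with the preset correlation calls unchanged lists here. The shares of genes recovered hold only for these numbers of changed genes and for equal spread in all libraries. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.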

Results

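Transcript levels were measured by sequencing of polyadenylated RNA in 143B cells, a human osteosarcoma line, at 0 h (control) and after 24 h or 48 h with 0.5 µM XD23, with 3 libraries per group. The title of the series names lower DKK1, a secreted inhibitor of Wnt signalling, and more active β-catenin signalling, so both were examined first. The libraries held 18341542 to 22901830 fragments, and 12910 to 13345 genes per library lay above 1 FPKM. Mitochondrially encoded transcripts took 27.3% to 29.5% of the summed FPKM in each library.

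The 48 h libraries lay apart from all others on the first principal component, with scores of 18.66 to 22.61 against -13.65 to -8.22 for the control and 24 h libraries. The third 24 h library lay apart on the second component, at -24.7, where the other 8 libraries lay between -6.96 and 9.06. In that library ribosomal protein genes averaged 8.29 on the log2 scale against 7.93 to 8.07 in the other 8, and nuclear genes of oxidative phosphorylation averaged 5.04 against 4.52 to 4.87.

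**Figure D1:**
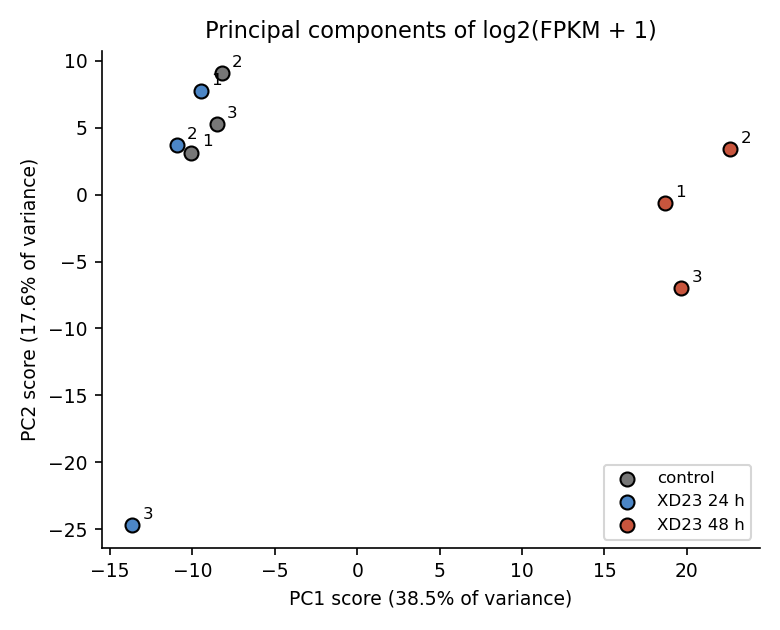
Scores of the 9 libraries on the first (38.5% of variance) and second (17.6%) principal components of log2(FPKM + 1), coloured by group and marked with the replicate number. The 48 h libraries score 18.66 to 22.61 on the first component, and the third 24 h library scores -24.7 on the second.

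DKK1 (ENSG00000107984, chromosome 10, 52314296 to 52318042, plus strand, GRCh38) fell after 48 h, from 20.88 ± 1.44 FPKM in control to 6.75 ± 0.223 FPKM (SD, n = 3), a 3.09-fold lower mean. After 24 h it stood at 20.34 ± 1.28 FPKM. The log2 fold change was -1.50 ± 0.06 at 48 h (limma, adjusted p = 6.36e-06) and -0.04 ± 0.06 at 24 h (adjusted p = 0.906). All 3 libraries at 48 h lay below all 3 controls, and the exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. At 24 h the exact permutation p was 0.8.

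**Figure D2:**
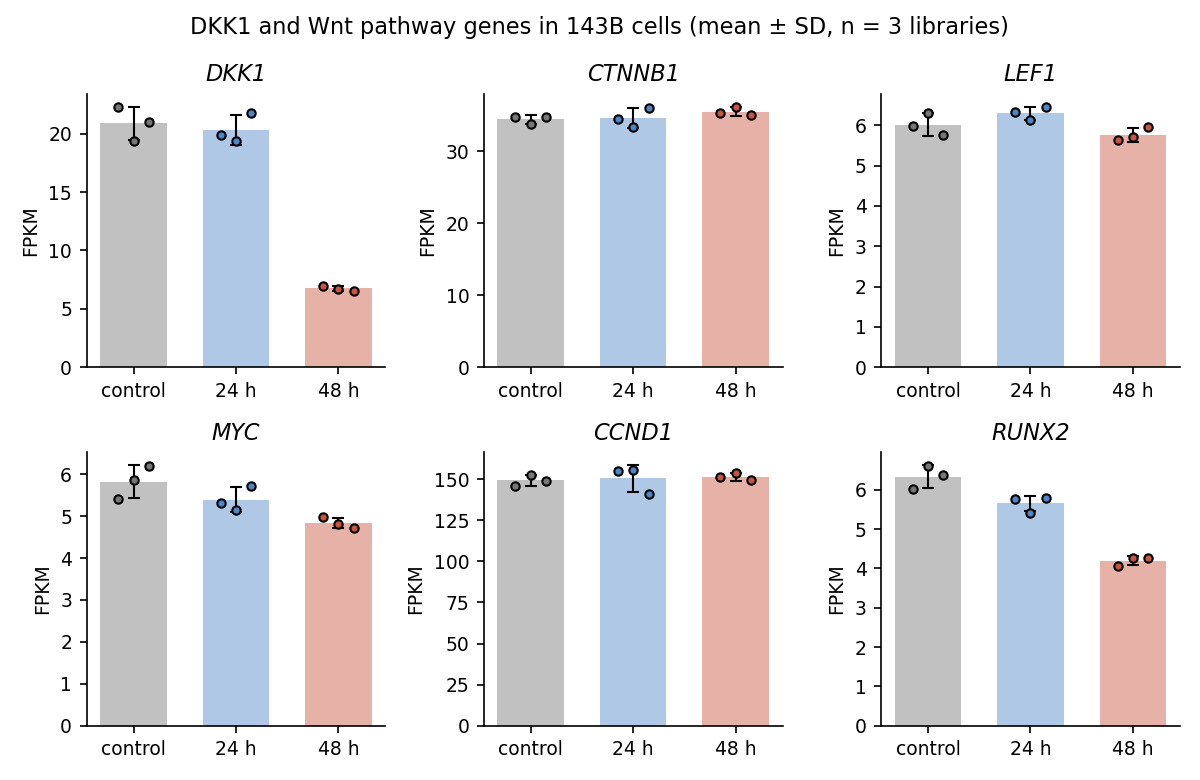
FPKM of DKK1 and 5 genes of the Wnt pathway or its targets in control cells and after 24 h and 48 h with XD23, where bars are means, error bars are SD and points are the 3 libraries of each group. DKK1 drops from 20.88 to 6.75 FPKM at 48 h, RUNX2 from 6.34 to 4.19 FPKM, and CTNNB1, LEF1 and CCND1 were not called at either time, except CTNNB1 at 48 h after quantile normalization (adjusted p = 0.0388).

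Genes commonly activated by β-catenin moved both ways after 48 h. Of 21 tested members of the target list, 5 rose, 4 fell and 12 were not called, with the same counts adjusted over the list alone. Over all 13657 genes tested, 1811 rose and 2080 fell, so calls both ways were not particular to this list. SNAI2, which drives mesenchymal traits, rose by 0.42 ± 0.07 on the log2 scale (12.08 to 16.56 FPKM), while RUNX2, the master regulator of osteoblasts, fell by 0.50 ± 0.05 (6.34 to 4.19 FPKM). MYC fell from 5.83 ± 0.394 to 4.84 ± 0.123 FPKM (log2 fold change -0.22 ± 0.06, adjusted p = 0.0168). The MYC call ended when control replicate 2 or 3 or 48 h replicate 2 or 3 was left out, with adjusted p from 0.0528 to 0.0623. CTNNB1, which encodes β-catenin, stood at 34.45 ± 0.618 FPKM in control and 35.5 ± 0.622 FPKM at 48 h (log2 fold change 0.04 ± 0.04, adjusted p = 0.443). After quantile normalization CTNNB1 was called higher at 48 h, by 0.10 against control (adjusted p = 0.0388) and by 0.10 against 24 h (adjusted p = 0.0384), while the other alternatives gave adjusted p of 0.228 to 0.958 and 0.0552 to 0.866. The pathway transcription factor LEF1 (-0.05 ± 0.04, adjusted p = 0.422) and the cyclin gene CCND1 (0.02 ± 0.04, adjusted p = 0.76) were not called either. AXIN2, a feedback inhibitor often read as a marker of the pathway, lay below the filter at 0.461 ± 0.0949 FPKM in control, 0.416 ± 0.0256 at 24 h and 0.356 ± 0.0483 at 48 h, on 33 to 60 fragments per library. The target list as a whole was not called (median log2 fold change 0.02, mean -0.04, camera adjusted p = 0.744), its median and mean differing in sign. DKK1 is itself a member and 1 of the 4 that fell, and the mean of the other 20 was 0.03.

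Wnt ligands and receptors included 8 genes that rose and 1 that fell among 21 tested (9 and 1 adjusted over the list alone). The ligand WNT7B rose by 0.40 ± 0.06 and the co-receptor LRP5 by 0.37 ± 0.11, while the receptor FZD2 fell by 0.36 ± 0.07. The list was called upward with a median of 0.12 (camera adjusted p = 0.00417; adjusted p = 0.0836 with an estimated correlation). In the list of the destruction complex and nuclear effectors of β-catenin, 8 of 31 genes rose and 0 fell, with the same counts adjusted over the list alone. They included the scaffold AXIN1 (0.30 ± 0.06), TCF7L1 (0.33 ± 0.07), a DNA-binding partner of β-catenin, and the corepressor TLE2 (0.30 ± 0.08). This list had a median of 0.07 (adjusted p = 0.0106; adjusted p = 0.211 with an estimated correlation), and its call ended after correction for gene length (adjusted p = 0.0652). The LRP5 call ended when any 1 of the 6 control and 48 h libraries was left out (adjusted p up to 0.101), and the TLE2 call with 5 of these 6. Among 5 tested Wnt antagonists, the secreted inhibitors SFRP1 (0.36 ± 0.04) and DKK3 (0.33 ± 0.06) rose and DKK1 fell. That list was not called (median 0.24, mean -0.08, adjusted p = 0.296), its median and mean differing in sign.

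The highest fold changes of protein-coding genes named by the rule at 48 h were those of ANGPTL4, DEPP1, STC1, ICAM1 and ADM. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 2.31 ± 0.624 to 21.84 ± 2.52 FPKM (log2 fold change 2.80 ± 0.16, adjusted p = 3.22e-05). DEPP1, a target of FOXO transcription factors, rose from 0.652 ± 0.176 to 6.05 ± 1.39 FPKM (2.08 ± 0.15). The secreted glycoprotein STC1 rose from 5.05 ± 0.479 to 18.8 ± 0.872 FPKM (1.71 ± 0.07). The adhesion molecule ICAM1 rose from 8.98 ± 0.674 to 26.51 ± 0.916 FPKM (1.47 ± 0.06), and the vasodilator peptide gene ADM from 6.26 ± 0.753 to 18.32 ± 2.18 FPKM (1.41 ± 0.10). At the other end, ANKRD1, a nuclear ankyrin protein induced by YAP, fell from 8.46 ± 0.893 to 1.76 ± 0.0896 FPKM (-1.77 ± 0.11, adjusted p = 3.79e-05). The other extremes were small RNAs or a pseudogene with few fragments or near-identical copies, and are uncertain. MT-TI, MIR5698 and MT-TS1 were higher on 0 to 45 fragments per library, and MIR5698 was listed at 0 in all 3 controls. MT-TI and MT-TS1 already stood as high at 24 h without being called, MT-TI at 3.07, 25.4 and 21.78 FPKM and MT-TS1 at 3.22, 10.52 and 11.89 FPKM in control, 24 h and 48 h. BCYRN1, SNORA63, RNA5SP434, RNU6-45P, RPL23AP64 and RNU6-611P were lower on 0 to 66 fragments. The SNORA63 call ended in 7 of 21 alternatives (adjusted p 0.0511 to 0.0871), among them leaving out control replicate 1, 2 or 3 or 48 h replicate 1 or 3. The RNU6-45P call ended in 4 of 21 (0.0528 to 0.0577), among them leaving out control replicate 1 or 48 h replicate 2 or 3, and the MT-TS1 call without a filter (0.051).

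**Figure D3:**
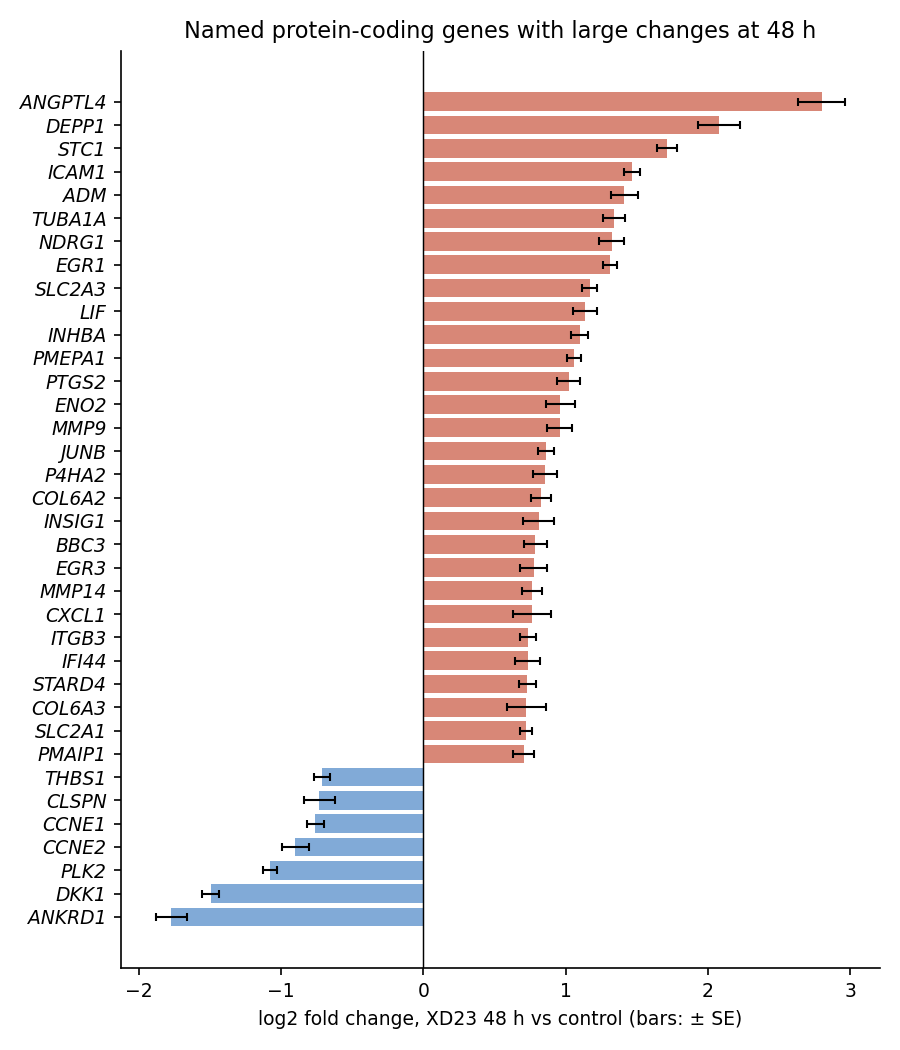
Log2 fold change of 36 of the named protein-coding genes with an absolute change of at least 0.7 at 48 h against control, with bars for 1 SE on each side (3 libraries per group). ANGPTL4 stands at 2.80 and ANKRD1 at -1.77, with 29 of the genes drawn higher and 7 lower.

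The lists of NF-κB targets, immediate early genes, secreted senescence genes, interferon genes and antigen presentation were called higher at 48 h. Of 22 NF-κB targets and cytokines, 20 rose, 0 fell and 2 were not called, with the same counts adjusted over the list alone. Besides ICAM1 these included the cytokine LIF (2.89 to 7.51 FPKM, 1.14 ± 0.08) and PTGS2, the inducible cyclooxygenase (8.41 to 18.15 FPKM, 1.02 ± 0.08). The list median was 0.63 (camera adjusted p = 1.94e-14; adjusted p = 0.0533 with an estimated correlation). Of 29 immediate early genes, 21 rose and 2 fell (23 and 2 adjusted over the list alone), led by the zinc finger factor EGR1 (30.0 ± 1.12 to 76.04 ± 2.9 FPKM, 1.31 ± 0.05), with the AP-1 member JUNB at 0.86 ± 0.06 and EGR3 at 0.78 ± 0.09. Their median was 0.38 (adjusted p = 1.01e-11; adjusted p = 0.0533 with an estimated correlation). Of 16 genes secreted by senescent cells, 9 rose and 2 fell (11 and 3 adjusted over the list alone), among them the chemokines CXCL1 (0.76 ± 0.13) and CCL2 (0.65 ± 0.11). Their median was 0.36 (adjusted p = 0.000624; adjusted p = 0.28 with an estimated correlation). In the type I interferon list 7 of 19 genes rose and 0 fell (8 and 1 adjusted over the list alone), led by IFI44 (0.73 ± 0.09) and the RNA sensor DDX60 (0.62 ± 0.06), with a median of 0.19 (adjusted p = 0.000374; adjusted p = 0.0533 with an estimated correlation). The interferon-induced modifier ISG15 rose by 0.41 ± 0.11. Its call ended without control replicate 3 or 48 h replicate 2 or 3 (adjusted p 0.0641 to 0.0657) and without a filter (0.0636). In antigen presentation 8 of 13 genes rose and 1 fell, with the same counts adjusted over the list alone, including the checkpoint ligand CD274 (0.45 ± 0.08). HLA-C (0.51 ± 0.06) and HLA-B (0.48 ± 0.10) share near-identical stretches and are uncertain. The median was 0.24 (adjusted p = 0.00203; adjusted p = 0.0925 with an estimated correlation).

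The lists of HIF targets, glycolysis, cholesterol synthesis and fatty acid synthesis were called higher at 48 h. Of 24 HIF targets, 20 rose and 1 fell (21 and 1 adjusted over the list alone), including ANGPTL4, ADM and NDRG1, a stress-responsive growth regulator (8.82 to 23.67 FPKM, 1.32 ± 0.09). Their median was 0.46 (adjusted p = 5.06e-14; adjusted p = 0.0545 with an estimated correlation). Of 21 glycolysis genes, 12 rose and 1 fell (14 and 3 adjusted over the list alone), among them the glucose transporters SLC2A3 (10.52 to 24.9 FPKM, 1.17 ± 0.05) and SLC2A1 (0.72 ± 0.04) and the enolase ENO2 (0.96 ± 0.10). The median was 0.24 (adjusted p = 6.51e-05; adjusted p = 0.0836 with an estimated correlation). Of 22 genes of the cholesterol synthesis list, 14 rose and 0 fell, with the same counts adjusted over the list alone. The sterol sensor partner INSIG1 rose by 0.81 ± 0.11 and the sterol transporter STARD4 by 0.73 ± 0.06. This list, with a median of 0.34 (adjusted p = 1.31e-09), was the single list of the 24 called at 48 h that held with an estimated correlation (adjusted p = 0.0304). In fatty acid synthesis 6 of 14 genes rose and 1 fell (7 and 1 adjusted over the list alone), including LPIN1 (0.58 ± 0.05), the desaturase SCD (0.34 ± 0.04) and FADS2 (0.33 ± 0.06), with a median of 0.18 (adjusted p = 0.00457; adjusted p = 0.156 with an estimated correlation).

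The lists of G1/S and DNA replication, DNA repair, ribosome biogenesis, tRNA synthetases and nuclear genes of oxidative phosphorylation were called lower at 48 h, while ribosomal proteins and mitochondrially encoded genes were not called. Of 52 genes of G1/S and DNA replication, 43 fell and 0 rose (46 and 0 adjusted over the list alone). The S-phase cyclins CCNE2 (4.98 to 2.21 FPKM, -0.90 ± 0.10) and CCNE1 (8.97 to 4.88 FPKM, -0.76 ± 0.06) and the checkpoint mediator CLSPN (-0.73 ± 0.11) were lowest. The median was -0.42 (adjusted p = 9.26e-20; adjusted p = 0.0533 with an estimated correlation). Of 28 DNA repair genes, 16 fell and 1 rose, with the same counts adjusted over the list alone, including the mismatch repair gene MSH6 (-0.56 ± 0.05), XRCC2 (-0.55 ± 0.10) and RBBP8 (-0.47 ± 0.04), both of homologous recombination. The median was -0.25 (adjusted p = 5.63e-06; adjusted p = 0.228 with an estimated correlation). Of 32 genes of ribosome biogenesis and MYC targets, 15 fell and 0 rose (16 and 0 adjusted over the list alone), including SRM, the spermidine synthase (-0.45 ± 0.06), and NHP2 (-0.40 ± 0.05). NPM1, a nucleolar protein with many pseudogenes and so uncertain, stood at -0.51 ± 0.05. The median was -0.18 (adjusted p = 7.71e-05; adjusted p = 0.0796 with an estimated correlation). Of 20 aminoacyl-tRNA synthetases, which charge tRNAs, 11 fell and 0 rose (12 fell and 1 rose adjusted over the list alone), including EPRS1 (-0.52 ± 0.05), FARSB (-0.50 ± 0.04) and WARS1 (-0.41 ± 0.03), with a median of -0.13 (adjusted p = 0.000139; adjusted p = 0.0796 with an estimated correlation). Of 50 nuclear genes of oxidative phosphorylation, 20 fell and 0 rose (23 and 0 adjusted over the list alone), among them COX7B (-0.53 ± 0.10), UQCRQ (-0.48 ± 0.12) and NDUFA4 (-0.48 ± 0.11), subunits of the respiratory chain. The median was -0.25 (adjusted p = 1.82e-06; adjusted p = 0.411 with an estimated correlation). The UQCRQ and NDUFA4 calls ended without control replicate 1 or 48 h replicate 2 (adjusted p 0.052 to 0.0602).

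The list of CDK inhibitors and arrest genes and that of p53 targets were called higher at 48 h. Of 19 CDK inhibitors and arrest genes, 10 rose and 2 fell, with the same counts adjusted over the list alone, including the transcription factors FOXO1 (0.53 ± 0.08) and KLF6 (0.50 ± 0.03). RBL1, a relative of RB1 that restrains E2F, fell by 0.49 ± 0.06. The median was 0.25 (adjusted p = 0.000612; adjusted p = 0.0533 with an estimated correlation). Of 28 p53 targets, 9 rose and 4 fell, with the same counts adjusted over the list alone. BBC3 (0.79 ± 0.08) and PMAIP1 (0.70 ± 0.07), which both encode BH3-only death proteins, rose, and the kinase gene PLK2 fell by 1.08 ± 0.05. The p53 list had a median of 0.06 (adjusted p = 0.0481; adjusted p = 0.165 with an estimated correlation), and its call ended in 10 of 23 alternatives, among them median-of-ratios scaling (adjusted p = 0.0591) and leaving out control replicate 2 (0.0942) or 24 h replicate 1 (0.0588), 2 (0.0501) or 3 (0.066).

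The lists of TGF-β targets, invasion, matrix, tubulins and heat shock were called higher at 48 h and epithelial markers lower. Of 19 TGF-β targets, 12 rose and 3 fell, with the same counts adjusted over the list alone. The activin subunit INHBA rose by 1.1 ± 0.06 and the feedback inhibitor PMEPA1 by 1.06 ± 0.05, while the matrix glycoprotein THBS1 fell by 0.71 ± 0.06. The median was 0.24 (adjusted p = 0.00193; adjusted p = 0.0836 with an estimated correlation). Of 27 invasion and mesenchymal genes, 10 rose and 5 fell (15 and 5 adjusted over the list alone), including the matrix proteases MMP9 (2.31 to 5.41 FPKM, 0.96 ± 0.09) and MMP14 (52.75 to 90.29 FPKM, 0.76 ± 0.07) and the integrin ITGB3 (0.74 ± 0.06), with a median of 0.17 (adjusted p = 0.00102; adjusted p = 0.0533 with an estimated correlation). Of 30 matrix and collagen genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone), including the collagen modifier P4HA2 (0.86 ± 0.09), COL6A2 (0.83 ± 0.07) and COL6A3 (0.72 ± 0.14), with a median of 0.16 (adjusted p = 0.0043; adjusted p = 0.4 with an estimated correlation). Of 10 tubulins, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.000559; adjusted p = 0.133 with an estimated correlation). TUBA1A (17.4 to 45.49 FPKM, 1.34 ± 0.08), TUBB4B (0.47 ± 0.03) and TUBB2A (0.43 ± 0.11) have near-identical copies and are uncertain, and the TUBB2A call ended without control replicate 2 or 3 or 48 h replicate 2 or 3. Of 19 heat shock genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with the chaperone genes HSPB1 at 0.41 ± 0.08, DNAJB1 at 0.32 ± 0.05 and HSPD1 at -0.36 ± 0.05 and a median of 0.12 (adjusted p = 0.00752; adjusted p = 0.185 with an estimated correlation). Of 5 epithelial markers, 3 fell and 0 rose (4 and 0 adjusted over the list alone), with the adhesion gene EPCAM at -0.38 ± 0.10 and a median of -0.34 (adjusted p = 0.0136; adjusted p = 0.211 with an estimated correlation). The keratins KRT8 (-0.45 ± 0.05) and KRT18 (-0.34 ± 0.06) have many pseudogenes and are uncertain, and the EPCAM call ended without control replicate 1 or 48 h replicate 1 or 2.

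Lists not called at 48 h included the YAP/TAZ targets (5 of 22 higher, 9 lower, 11 lower adjusted over the list alone, median -0.15), G2/M and mitosis (5 of 53 higher, 11 lower, median -0.06), the ATF4 and integrated stress response (10 of 29 higher, 14 lower, median -0.14) and metallothioneins (1 of 6 higher, 3 lower, median -0.27). Also not called were pro-apoptotic genes (5 of 28 higher, 2 lower), anti-apoptotic genes (4 of 14 higher, 1 lower), the unfolded protein response (5 of 27 higher, 3 lower), NRF2 targets (2 of 22 higher, 6 lower) and ferroptosis regulators (5 of 19 higher, 5 lower, with median -0.03 and mean 0.05 of opposite sign). Mitochondrially encoded genes (4 of 13 higher, 2 lower), ribosomal proteins (0 of 53 higher, 1 lower), replication dependent histones (2 of 14 higher, 2 lower), osteoblast and bone matrix genes (3 of 10 higher, 4 lower, with median 0.12 and mean -0.03 of opposite sign), autophagy and lysosome genes (7 of 30 higher, 3 lower, with a test of opposite sign to the median of -0.04), Notch genes (4 of 15 higher, 1 lower) and Hedgehog genes (1 of 7 higher, 1 lower) completed the set. Markers of other cell types had too few members above the filter for a list test. Among leukocyte markers 1 gene passed the filter, CD3D at 0.744, 1.18 and 0.337 FPKM in control, 24 h and 48 h. Among endothelial markers TIE1 (12.2 FPKM in control, 16.3 at 48 h, called) and ERG passed, and among adipocyte and chondrocyte markers SOX9 (35.3 and 52.8 FPKM, called), PPARG (2.55 and 3.27 FPKM, called) and LPL passed, while PECAM1, VWF, PTPRC, COL2A1 and ACAN stayed below 1 FPKM on average in each group.

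**Figure D4:**
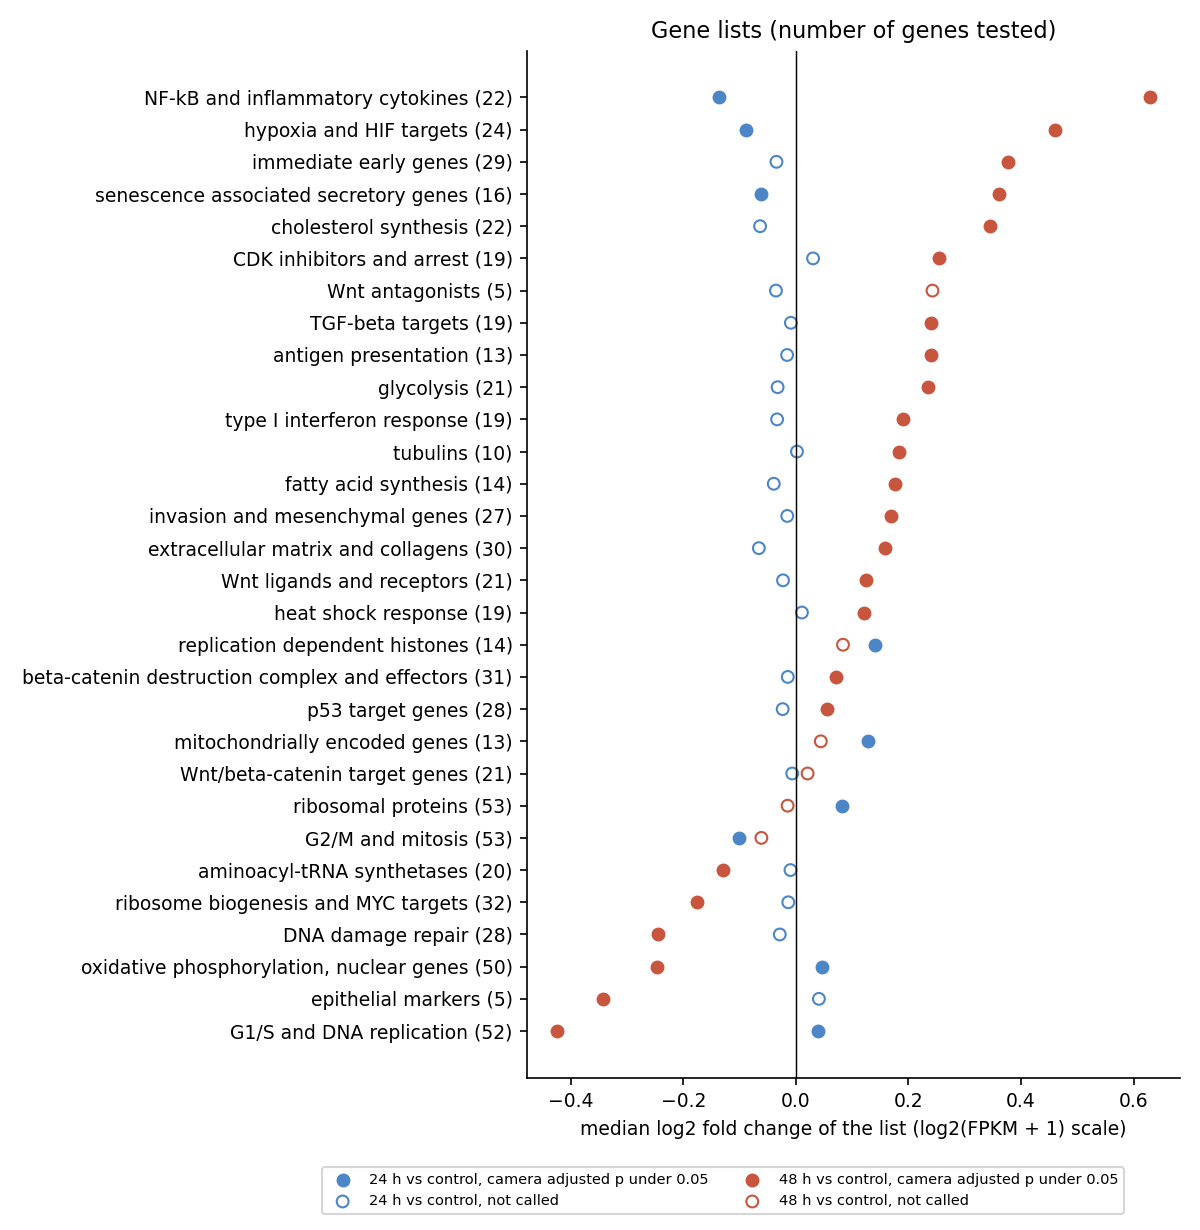
Median log2 fold change of 30 fixed gene lists at 24 h (blue) and 48 h (red) against control, with the number of tested genes in brackets, where filled points passed camera with the preset correlation and open points did not. The NF-κB list stands at 0.63 and the G1/S list at -0.42 at 48 h, and at -0.14 and 0.04 at 24 h.

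In all, 3891 of 13657 genes were called at 48 h against control, 1811 higher and 2080 lower (46.5% higher), and 64 of them changed by at least 1 on the log2 scale, 35 higher and 29 lower (21 and 5 among protein-coding genes). After median-of-ratios scaling 2155 were higher and 1617 lower (57.1% higher), so which direction held more genes depended on the scaling. The median absolute change of called genes was 0.30. The 3 values of each group did not overlap for 6884 genes (50.4%, with 10% expected by chance). Without 48 h replicate 2, 2551 genes were called.

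After 24 h few genes were called. RNU6-548P, a U6 small nuclear RNA copy, was the 1 gene called by limma (6.81 ± 0.628 to 3.51 ± 0.139 FPKM, log2 fold change -0.79 ± 0.07, adjusted p = 0.032), on 8 to 18 fragments per library and with near-identical copies, so it is uncertain. MYC stood at 5.40 ± 0.298 FPKM (-0.09 ± 0.06, adjusted p = 0.737), LEF1 at 6.30 ± 0.164 FPKM (adjusted p = 0.8), CTNNB1 at 34.61 ± 1.33 FPKM (adjusted p = 0.98) and CCND1 at 150.5 ± 8.09 FPKM (adjusted p = 0.963). An unadjusted p under 0.05 was reached by 1015 genes, and the groups did not overlap for 1802 genes (13.2%, with 10% expected by chance). With voom weights on whole fragments 0 genes were called, and with array weights, which gave the third 24 h library a weight of 0.184, 46 genes. The RNU6-548P call ended in 13 of 22 alternatives, among them leaving out any 1 of the 3 libraries at 24 h.

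Gene lists shifted by small amounts at 24 h, with 0 members called over all genes by limma as reported in any of the 9 called lists. Genes of G2/M and mitosis were lower as a list (53 genes, median -0.10, camera adjusted p = 1.46e-10), the 1 list whose call held with an estimated correlation (adjusted p = 0.0418), with 2 members lower adjusted over the list alone. Fry, which tests a list against no change and not against other genes, also called it (adjusted p = 0.00607). NF-κB targets (median -0.14, 8 members lower adjusted over the list alone), HIF targets (-0.09, 0 members) and secreted senescence genes (-0.06, 6 lower) were lower as lists, with adjusted p of 0.452, 0.515 and 0.67 with an estimated correlation. With array weights, and with voom weights without the third 24 h library, the NF-κB members CXCL8 (-0.50 and -0.61), IL1B (-0.46 and -0.49) and IL1A (-0.30 and -0.31) were called lower and the mitochondrial genes MT-ND1 (0.26 and 0.24) and MT-CYB (0.25 and 0.23) higher. The mitochondrial tRNA gene MT-TI, on few fragments, was also called higher by the latter (3.61), against 3.10 ± 0.59 and adjusted p = 0.3 as reported. Mitochondrially encoded genes (13 genes, median 0.13, 6 higher adjusted over the list alone), replication dependent histones (0.14, 0 members) and G1/S genes (0.04, 0 members) were higher as lists, with adjusted p of 0.452, 0.452 and 0.665 with an estimated correlation. Ribosomal proteins (0.08, 0 members) and nuclear genes of oxidative phosphorylation (0.05, 0 members) were also called upward, with adjusted p of 0.79 and 0.887 with an estimated correlation, and both were highest in the third 24 h library. Without that library their medians were -0.01 (adjusted p = 0.997) and -0.04 (adjusted p = 0.133). The call of mitochondrially encoded genes ended with quantile normalization (median 0, adjusted p = 0.663). That of histones ended without a filter (median 0.03, adjusted p = 0.117), with array weights (0.0515) and with voom weights without the third 24 h library (0.137). The list of senescence genes lost its call without 24 h replicate 1 (adjusted p = 0.426) or 2 (0.111), and that of oxidative phosphorylation without control replicate 2 (0.192). The 4 Wnt lists were not called at 24 h, with medians of -0.04 for antagonists, -0.01 for target genes, -0.02 for ligands and receptors and -0.01 for the destruction complex, and with a test pointing up for the target and ligand lists although their medians and means were negative. No other list was called at 24 h.

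The direct comparison of 48 h with 24 h tests whether the responses differ, since both share the control. DKK1 was lower at 48 h than at 24 h (-1.46 ± 0.06, adjusted p = 5.04e-06, 3 of 3 libraries), as were ANKRD1 (-1.52 ± 0.11) and FAM111B, a replication-linked protease gene (9.40 to 3.15 FPKM, -1.34 ± 0.10). ANGPTL4 (3.31 ± 0.16), DEPP1 (2.39 ± 0.15), STC1 (2.04 ± 0.07), ICAM1 (1.61 ± 0.06), ADM (1.58 ± 0.10) and NDRG1 (1.51 ± 0.09) were higher. The metallothionein MT1E (77.27 to 39.23 FPKM, -0.96 ± 0.08) was lower, although its near-identical relatives make it uncertain, and the chemokine CXCL8 was higher (19.03 to 40.07 FPKM, 1.05 ± 0.12). Of 22 NF-κB targets 22 were higher at 48 h than at 24 h (22 adjusted over the list alone, median 0.85), of 24 HIF targets 20 (20 over the list alone, median 0.56), and of 52 G1/S genes 45 were lower (46 over the list alone, median -0.47), with adjusted p of 0.0749 for each with an estimated correlation. Cholesterol genes (15 of 22 higher, 16 adjusted over the list alone, median 0.41) were the 1 list of 25 called that held with an estimated correlation (adjusted p = 0.0365). Metallothioneins (3 of 6 lower, 5 adjusted over the list alone, median -0.34, adjusted p = 0.0463; adjusted p = 0.308 with an estimated correlation) and ribosomal proteins (6 of 53 lower, 0 adjusted over the list alone, median -0.11, adjusted p = 0.00411; adjusted p = 0.67 with an estimated correlation) were also called lower. Both calls ended without 24 h replicate 3 (adjusted p = 0.0825 and 0.67), the metallothionein call in 10 of 22 alternatives (adjusted p 0.0509 to 0.0833) and the ribosomal call in 5 of 23 (0.0517 to 0.67). Wnt ligands and receptors (6 of 21 higher, 1 lower, median 0.11; adjusted p = 0.122 with an estimated correlation) and the destruction complex list (10 of 31 higher, 1 lower, median 0.08; adjusted p = 0.266 with an estimated correlation) were called higher, and Wnt target genes (4 of 21 higher, 5 lower, median 0.01, adjusted p = 0.994) were not. The destruction complex call ended without 24 h replicate 3 (adjusted p = 0.0577), with voom weights without that library (0.0575) and after correction for gene length (median 0.04, adjusted p = 0.23). In this comparison 4415 genes were called, 2188 higher and 2227 lower. After median-of-ratios scaling 2363 were higher and 1988 lower, so here too the direction with more genes depended on the scaling. Of the 4415 genes 69 changed by at least 1 on the log2 scale (54 higher and 15 lower, with 37 and 3 among protein-coding genes). The groups did not overlap for 6302 genes (46.1%, with 10% expected by chance). The lowest fold changes also included small RNAs on at most 66 fragments (BCYRN1, RNU7-49P, SNORD100, RNU6-45P and Metazoa_SRP) and the highest MIR3124 and Y_RNA, all uncertain.

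Across the 13657 genes, which are not independent replicates, the 24 h and 48 h fold changes correlated with r = 0.21. In 100 simulations of unchanged groups that share the controls r was 0.50 (0.463 to 0.535). Changes at 48 h alone lower r below that value, whatever happened at 24 h, so the covariance is given beside it. The covariance was 0.0086, against 0.008 (0.007 to 0.009) simulated. Among protein-coding genes r was -0.11 and the covariance -0.0021, against 0.0026 simulated. The simulations drew genes independently, so their ranges are narrower than genes that move together would give and are no test of the covariance. With 1 gene called at 24 h the overlap of calls could not exceed 1; it was 0, where independent lists would share 0 higher and 0.15 lower genes. With 3 controls, no split leaves 2 libraries in each part, so the controls were not split.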

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

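The tests of explanations and the splits of the libraries in this part were chosen after the results were seen, while the comparison of 48 h with 24 h was planned.

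DKK1 fell at 48 h (log2 fold change -1.50) while the 21 tested Wnt target genes moved both ways (5 higher, 4 lower). All 13657 tested genes also did so (1811 higher, 2080 lower). Scaling as the source of the DKK1 change is argued against by its highest value over the alternatives, -1.44, with -1.62 as the lowest. The filters on low values left it at -1.50, but they cannot alter the fold change of a gene that passes them. A general 1.2-fold rise of the target genes would be 0.26 on a log2 scale without a pseudocount. It would be less on log2(FPKM + 1), above all for genes with low values. Simulated lists of 25 genes raised 1.2-fold had medians of 0.22 and 0.21 on that scale. The 20 tested targets other than DKK1 had a mean of 0.03 and a median of 0.024. The 95% limits of the mean, from the spread between libraries, were -0.008 and 0.067. These values argue against such a rise of the 20 as a set. The SD over these genes was 0.23, so a rise of single members stays open. Targets left out by the filter on low values cannot be told apart from unmoved ones. Of the 13 below the filter 0 were called higher and 0 lower (limma without a filter), and they lie near the floor. It stays open that β-catenin protein changed or that targets outside the list moved, and no biological explanation was tested, because the design has no untreated cells at 48 h.

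At 48 h 3891 genes differed from control and at 24 h 1, and the direct comparison of 48 h with 24 h called 4415. A steady drift since 0 h would give a slope of 0.5 of the 24 h on the 48 h changes, and the slope was 0.059 over genes called at 48 h, with 0.083 as the highest value without 1 library. The scaling of the libraries as the whole source is argued against by the 88.1% of those genes that were also called after median-of-ratios scaling. Each 48 h library was treated, so a change of the cultures after 24 h cannot be told apart from a late action of XD23. Such a change, in density or spent medium for example, could lower YAP/TAZ targets, which respond to density, and raise HIF targets. This expectation was written after the list values had been seen, so the values that follow are no support for it. Of 22 YAP/TAZ targets 9 were lower and 5 higher (median -0.15, camera adjusted p = 0.11). Of 24 HIF targets 20 were higher and 1 lower (median 0.46, camera adjusted p = 5.06e-14, and 0.0545 with an estimated correlation). For 3 against 3 libraries there are 10 splits, too few for a share under 0.05: as many genes as in the real grouping were called in 3 splits for 24 h against control (real 1, highest other 1), 1 for 48 h against control (real 3891, highest other 0) and 1 for 48 h against 24 h (real 4415, highest other 1).

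The third 24 h library stood apart from the other 2 of its group, at -24.7 on the second principal component, with ribosomal protein genes at a mean of 8.29 on the log2 scale against 7.99 and 8.02. Its deviations followed gene length (rank correlation -0.505, the strongest of the 9 libraries, with medians of 0.106 in the shortest group of genes at 439 bases, 0.177 at 1753 bases and -0.18 at 12163 bases), so length bias may be part of the source, but as the whole source it is argued against by a mean squared deviation of 0.0465 after a correction for length (0.0576 before), where the highest other library had 0.0235. A 48 h library under a 24 h label is argued against by its position of 0.064 between the control mean at 0 and the 48 h mean at 1, where the 48 h libraries started at 0.901. RNA from other cells cannot be told apart from this, since 0 genes lay at 5 FPKM or more here and under 1 in the other 8, but every other library also had 0 and a small share would lift none so far; differences in RNA quality, preparation or culture may remain, and no biological explanation was tested.

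The following results differ between the 24 h and 48 h responses by the direct test, all as log2 differences of 48 h minus 24 h. Inflammation and secretion lists had medians of 0.85 (NF-κB), 0.45 (immediate early), 0.35 (secreted senescence genes), 0.17 (interferon) and 0.28 (antigen presentation). Metabolic lists stood at 0.56 (HIF targets), 0.27 (glycolysis), 0.41 (cholesterol), 0.24 (fatty acid synthesis) and -0.29 (oxidative phosphorylation). Growth lists stood at -0.47 (G1/S), -0.22 (DNA repair), 0.24 (CDK inhibitors and arrest genes), -0.13 (tRNA synthetases), -0.11 (ribosomal proteins) and -0.15 (ribosome biogenesis). Signalling and structure lists stood at 0.11 (Wnt ligands and receptors), 0.08 (destruction complex), 0.25 (TGF-β), 0.21 (matrix), 0.14 (invasion), 0.17 (tubulins), 0.12 (heat shock), -0.34 (metallothioneins) and -0.40 (epithelial markers). The heat shock call ended without 24 h replicate 1 (adjusted p = 0.0806) and among protein-coding genes (0.0767). The cholesterol list alone among these held with an estimated correlation (adjusted p = 0.0365). Genes stood at 3.31 (ANGPTL4), 2.39 (DEPP1), 2.04 (STC1), 1.61 (ICAM1), 1.58 (ADM), 1.51 (NDRG1), -1.52 (ANKRD1), -1.46 (DKK1) and -1.34 (FAM111B). Another 97 named genes also differed, but most were named because they were called in these same comparisons, so that number is no separate result.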

How the results depend on the processing

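The tests with voom weights, the correction for gene length and the restriction to protein-coding genes were chosen after the results were seen, and the other alternatives were planned.

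At 24 h the count of 1 called gene became 3 without a filter, 4 with quantile normalization, 46 with array weights and 15 with voom weights without the third 24 h library. It became 0 without a trend, with only the groups compared, with the replicate block, with voom weights, with the length correction, among protein-coding genes and at an absolute log2 fold change of at least 1 (limma with the trend had 1015 genes at an unadjusted p under 0.05), and 0 to 2 when 1 library was left out. At 48 h 3891 became 5875 with voom weights without the third 24 h library, 64 at an absolute change of at least 1, and 2551 (without 48 h replicate 2) to 5136 (without 24 h replicate 3) when 1 library was left out. For 48 h against 24 h 4415 became 69 at an absolute change of at least 1 and 2946 to 4600 when 1 library was left out. The replicate block gave 3733 and 4344 genes for the comparisons at 48 h. With an estimated correlation 1 list was called in each comparison, while fry, which tests lists against no change and not against other genes, called 1 list at 24 h and 35 in each comparison at 48 h. The correlation of the 24 h and 48 h responses, 0.21, became 0.31 with a pseudocount of 0.1, 0.33 without a filter, 0.05 at 5 FPKM, -0.11 among protein-coding genes and 0.169 to 0.285 when 1 library was left out. CTNNB1, not called as reported, was called at 48 h after quantile normalization (0.0987 against control, 0.097 against 24 h). DKK1 at 48 h stayed between -1.55 and -1.45 when 1 library was left out. The 24 h median of oxidative phosphorylation turned from 0.05 to -0.0181 with array weights and -0.0429 with voom weights without the third 24 h library, and ran from -0.0399 (without that library) to 0.1111 when 1 library was left out. That of ribosomal proteins turned from 0.08 to -0.0087 with voom weights without the third 24 h library. The cause of these turns was not tested beyond the third 24 h library. Leaving aside the estimated correlation, fry and the threshold on the fold change, 77 of the 88 called genes that the naming rule picked, which are extremes or leaders of lists, and 22 of 24 lists kept their calls in each alternative run at 48 h against control, 83 of 89 and 21 of 25 at 48 h against 24 h, and 0 of 1 and 4 of 9 at 24 h. Over all called genes fewer kept theirs: without 48 h replicate 2, 2498 of 3891 and 2897 of 4415.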

Other observations

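The tests of gene families and of the covariance among protein-coding genes in this part were chosen after the results were seen, as were the genes named here from lists that were not called.

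Some lists that were not called at 48 h hold members that moved strongly in opposite directions. Among YAP/TAZ targets the matricellular genes CCN2 (161.4 to 86.56 FPKM, log2 fold change -0.89 ± 0.06) and CCN1 (-0.50 ± 0.05) fell with ANKRD1, while the ectonucleotidase NT5E (0.42 ± 0.04) rose. In the ATF4 list the serine synthesis gene PSAT1 (419.2 to 297.4 FPKM, -0.49 ± 0.05) and the cystine transporter SLC7A11 (-0.47 ± 0.08) fell, and the growth inhibitor DDIT4 (88.18 to 160.7 FPKM, 0.86 ± 0.08) and the glutathione-degrading enzyme CHAC1 (0.51 ± 0.07) rose. Among bone genes SPP1 (-0.62 ± 0.07) and SPARC (-0.56 ± 0.04), both of bone matrix, fell and the osteoblast cadherin CDH11 (0.53 ± 0.04) rose. In the Notch list the ligand JAG1 (0.66 ± 0.07) and the effector HES1 (0.65 ± 0.04) rose, while the feedback gene NRARP (-0.54 ± 0.10) fell.

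Families grouped by symbol were tested at 48 h, and those named here were picked after the results were seen. Some share members with the fixed lists, such as the MCM genes with the G1/S list. Of 47 mitochondrial ribosomal proteins of the large subunit 22 fell, with MRPL1 at -0.71 ± 0.08, and of 10 MCM family genes 8 fell, including the helicase subunit MCM5 (-0.52 ± 0.06). Of 11 SR splicing factors 8 fell, with SRSF10 at -0.37 ± 0.04. Of 13 KLF transcription factors 7 rose, led by KLF10 (0.66 ± 0.05), KLF2 (0.66 ± 0.09) and KLF9 (0.64 ± 0.05). Of 15 KDM histone demethylases 8 rose, with KDM6B at 0.65 ± 0.09, and of 16 DUSP phosphatases 7 rose, with DUSP6 at 0.57 ± 0.05. Of 119 families tested with camera at the preset correlation 20 were called, 8 higher and 12 lower, and 0 with an estimated correlation (adjusted p = 0.51 to 0.723 with an estimated correlation for the 6 families named).

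The 24 h and 48 h changes of protein-coding genes were nearly uncorrelated (r = -0.11, and -0.029 without the third 24 h library, -0.035 and -0.039 without control replicate 2 or 3), where simulated unchanged groups that share the controls gave 0.50. Changes at 48 h alone would also lower r from that value. The covariance of protein-coding genes was -0.0021. It ran from -0.0034 (without 24 h replicate 1) to -0.0006 (without the third 24 h library). Simulations of unchanged groups gave 0.0024 to 0.0028. They drew genes independently, with 1 spread per gene for all 9 libraries. Measured genes move together and the third 24 h library spread more widely, so the simulated range is no test of the covariance. Over all 13657 genes the covariance was 0.0086, within the simulated 0.007 to 0.009. NF-κB targets as a list had a median of -0.14 at 24 h and 0.63 at 48 h, and HIF targets -0.09 and 0.46. No explanation of this pattern was tested.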
